A study of Oryza sativa with 4 samples.

How the data were processed

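RNA was taken from young leaves of 2 sibling plants of 1 double knockdown line and 2 sibling plants of 1 empty-vector line. It was extracted with Trizol and labelled with Cy3 or Cy5 by a linear amplification kit, per the labels. Each knockdown plant was paired with 1 control plant on 2 arrays with exchanged dyes, on the Agilent rice array of design 015241. All 4 arrays lay on 1 slide with 1 scan date, so there was no batch to test. An aligner or genome build does not apply to these arrays, and gene identities and descriptions were those given in the files.

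Per the file headers, the authors' spot intensities were made with Feature Extraction 9.1.3.1 (protocol GE2-v5_91_0806), as mean brightness per spot and channel, local background, and a processed signal after background subtraction, spatial detrending and lowess dye normalization. The deposited log10 ratios came from those processed signals, and the columns of the series-wide table held log10 of knockdown over control on all 4 arrays. The scale and direction of that table were found by comparison with the scanner ratios (r from 0.996 to 1.00), and its median was 0 on each array. The deposited p-values were those of Feature Extraction's error model for a single array and were not used here. No deposited column was left without a sample (0).

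Mean intensities were background-corrected in limma by normexp with an offset of 50 and normalized within arrays by loess, with control spots given no weight. Spots called non-uniform or population outliers in either channel were left out, and the spots of a probe were averaged. The array held 43144 spots for 42418 probes after removal of control spots. Probes were kept when well above background in 1 line on all 4 arrays, which left 30351, of which 30012 had values for both pairs. Median signals of the arrays were 251 to 389 in Cy3 and 417 to 637 in Cy5, against background medians of 58.5 to 61.0 and 61.0 to 64.0. For comparisons between plants, channel values were scaled between arrays by the Aquantile method and averaged per plant.

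Ratios were turned to knockdown over control and the dye-swapped arrays of a pair were averaged, which left n = 2 pairs and 1 residual degree of freedom. Pairing follows the shared hybridisation, and the deviations of same-numbered plants correlated with r = 0.333. A moderated test in limma (prior degrees of freedom 2.19) was applied to each probe, two-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05, and the SE is the moderated one. Because the plants of a line were siblings, the p-values cover the spread between these plants and not between lines. Probes over 2-fold on all 4 arrays were counted without a test. For a probe well above background on all 4 arrays of one line and on none of the other, the dim channel was raised to at least the lowest signal of any probe well above background in that channel, and the resulting ratio is given as a bound.

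Gene lists were patterns on the descriptions, with the brightest probe of each gene and at least 5 measured genes. They covered transposable elements, DNA methylation and RNA silencing, chromatin, histones, photosystems, carbon fixation, ribosomal proteins, NBS-LRR genes, pathogenesis-related genes, WRKY factors, receptor-like kinases, jasmonate, diterpenoids, phenylpropanoids, heat shock, LEA proteins, redox, cytochrome P450, F-box proteins, clock and flowering, dividing cells, seed storage, pollen and flower, root, auxin, cell wall, sugar and starch, and NAC factors. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 28 lists, and again with an estimated correlation and with fry. With an estimated correlation camera used the 1 residual degree of freedom. It could then hardly call any list, so its result does not decide whether a list shifted. Control-plant differences are control plant 1 minus control plant 2. Named genes were the 12 largest rises and 12 largest falls among called genes with a functional description and 1 direction on all 4 arrays, the 2 largest each way with any description, and up to 3 called members per list with the largest change. The 3 photosystem members that fell were named in addition.

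The comparisons, lists, naming rule and alternatives were chosen before the data were examined. Alternatives covered the scanner software's processed signals, the deposited table, median centring, no background subtraction, an offset of 0, no filter and a stricter filter on dim probes, outlier and saturated spots, independent arrays, fits with and without the pair, a variance trend, each plant or pair left out, and other thresholds. The model with a random pair and a dye term could not be fitted with 4 arrays, and a random pair without a dye term was added after the data were seen. On simulated data with 30012 probes and 2 pairs, 0% of changes were recovered when few probes changed (60 to 71 for each size of change). When a large part of the probes changed, 84.8% of 2-fold, 97.0% of 4-fold and 98.7% of 8-fold changes were recovered and 3.22% of calls were false. With no list raised, 0 of 28 simulated lists were called by camera, and 1 when 1 list was raised 2-fold. Simulated probes were drawn independently of one another, so these error rates do not cover correlation between genes. In the data that correlation was estimated at 0.41 for the photosystem list and 0.31 for the ribosomal list. R 4.3.3 was used with limma 3.58.1, statmod 1.5.0 and data.table (version 1.17.8).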

Results

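Transcript levels were measured in young leaves of 2 transgenic rice lines of the cultivar Nipponbare. In the knockdown line, hairpin RNA constructs targeted both OsMOM1a and OsMOM1b, the rice relatives of Arabidopsis MOM1, a nuclear protein that keeps transposable elements and transgenes silent. The control line carried the empty vector. Each line was represented by 2 sibling plants raised in a greenhouse for about 2 months and sampled before the boot stage, so that n = 2 pairs of plants throughout. Each pair of plants, 1 of each line, was hybridised on 2 arrays with the dyes exchanged, which gave 4 arrays of 42418 probes for 29690 loci. Between 69.0% and 71.7% of spots were well above background in a channel, no spot was saturated (0 on all 4 arrays), and 107 to 201 spots per array were left out as outliers. The number of plants limits the precision. The comparison asks which transcripts depend on the OsMOM1 genes, and a line effect cannot be told apart from the knockdown because each construct was studied in 1 line.

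A large part of the leaf transcriptome differed between the lines. Of 30012 probes tested, 6015 were higher and 4948 were lower in the knockdown plants, corresponding to 3957 higher and 3455 lower genes among 20386. With the processing used here, more of the extreme changes were rises: 182 probes were more than 16-fold higher and 64 more than 16-fold lower. That count was not repeated with other processing. A gene for a conserved hypothetical protein (Os03g0782200) and the root-specific gene RCc2 (Os04g0612500) had the largest rises, and a metallothionein gene (Os05g0202800) was among the genes that fell strongly. Beyond the model, 2959 probes were over 2-fold higher on all 4 arrays and 1705 over 2-fold lower, against 20 that exceeded 2-fold in opposite directions in the 2 pairs. With the scanner software's signals these counts were 3606 higher, 3180 lower and 32 opposite, so that the excess of rises was smaller. Log2 ratios of the 2 pairs correlated across probes with Pearson's r = 0.876 and Spearman's rho = 0.870, where probes are not independent replicates. Among 6115 genes with several tested probes, 12 had probes called in both directions. All calls rest on limma's moderated test with Benjamini-Hochberg adjustment over the tested probes, and 15595 probes had an unadjusted p under 0.05. No probe was called without knockdown plant 1 (0 calls, 8492 probes at an unadjusted p under 0.05, lowest adjusted p = 0.0644) or without knockdown plant 2 (0 calls, 8284 probes, lowest adjusted p = 0.0654), because the spread then came from the control plants alone, and this covers every gene named below. Without control plant 1 the counts were 10261 higher and 9136 lower, and without control plant 2 they were 10431 and 9533. The balance of directions depended on the scaling: 54.9% of called probes were higher here, but 45.6% with the scanner software's own signals and 44.0% with median centring, where the median log2 ratio of all probes moved from 0.03 to -0.09 and -0.13.

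**Figure D1:**
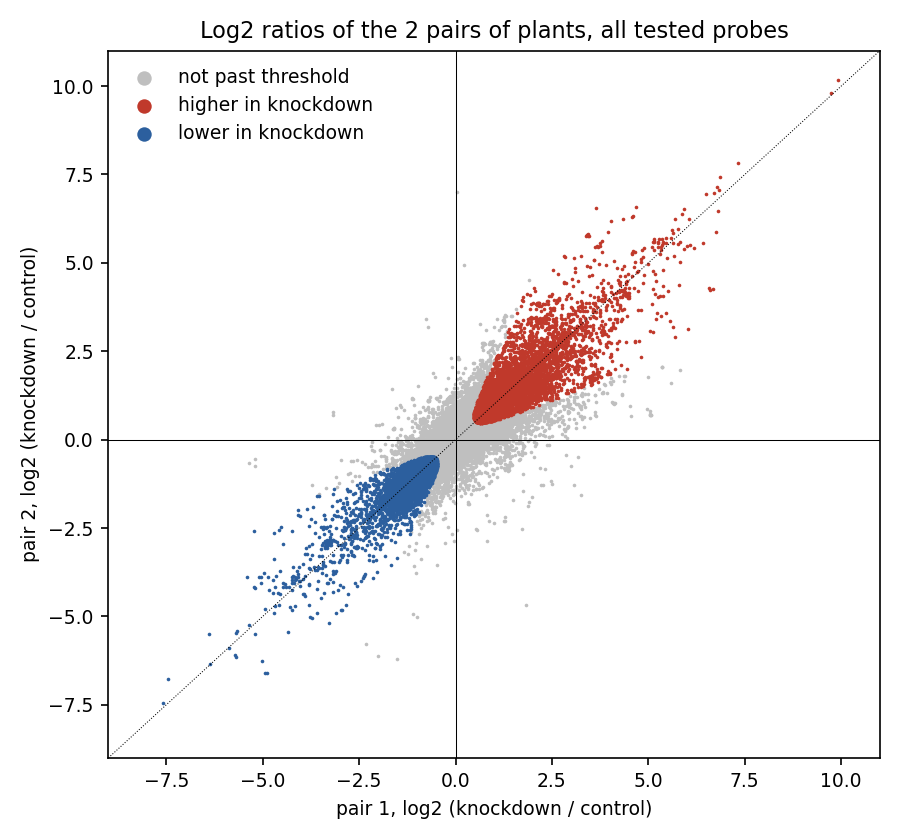
Log2 ratio of knockdown over control for every tested probe in pair 1 (horizontal axis) and pair 2 (vertical axis), each the mean of 2 dye-swapped arrays. Red points are the 6015 higher and blue points the 4948 lower probes, grey points did not pass, and the dotted line marks equal ratios, with r = 0.876 across probes.

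The largest rises were those of a gene without a known function and of a root gene. RCc2, described as a root-specific protein, was 874-fold higher (log2 ratio 9.77 ± 0.12, SE, n = 2 pairs; adjusted p = 0.0107), and Os03g0782200 was 1058-fold higher (10.05 ± 0.14; adjusted p = 0.0107). Chalcone synthase (Os11g0530600), which makes the first flavonoid skeleton, was at least 109-fold higher, and a multicopper oxidase gene (Os01g0850700), of the family of laccases and ascorbate oxidases, at least 175-fold. Neither was well above background on any control array. A pair of genes named CRT/DRE binding factor 1, transcription factors of the cold response, were higher. Os04g0572400 rose by log2 5.81 ± 0.24, while the fold of Os02g0677300 was not measured because it was well above background on only 2 of 4 control arrays. A beta-1,3-glucanase gene (Os01g0713200), whose product cuts callose and fungal wall glucans, rose 63.6-fold, and all 6 of its probes were called higher. The wall-loosening expansin OsEXPA2 (Os01g0823100) rose 51.9-fold and a xyloglucan endotransglucosylase gene (Os06g0697000), whose product cuts and rejoins wall polymers, 48.6-fold. Peroxidase genes rose 71.3-fold (Os01g0294700) and at least 41.5-fold (Os10g0109300), a UDP-sugar transferase gene (Os06g0289900) 99.4-fold and an esterase or lipase gene (Os07g0162700) at least 52.9-fold. The glucanase, expansin, sugar transferase and first peroxidase genes were well above background on 3 of 4 control arrays. Adjusted p-values of these 13 genes were 0.0107 to 0.0110.

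Strong falls included those of a metallothionein and a phosphodiesterase gene. The metallothionein gene Os05g0202800, coding for a small cysteine-rich metal-binding protein, had a log2 ratio of -7.52 ± 0.12 (184-fold lower, n = 2 pairs; adjusted p = 0.0107). A glycerophosphodiester phosphodiesterase gene (Os02g0514500), which releases glycerol phosphate from deacylated lipids, followed at -7.12 ± 0.23 (139-fold lower; adjusted p = 0.0107). The gene for a synthase of monogalactosyldiacylglycerol (Os08g0299400), the main galactolipid of chloroplast membranes, was 26.0-fold lower, as was a glycosyl transferase gene (Os01g0142300). A thiazole biosynthetic gene of thiamine synthesis (Os07g0529600) was 29.3-fold lower, and the low-temperature-induced gene lt101.2 (Os03g0286900) 58.8-fold, while CRT/DRE binding factor genes of the same cold response rose. A sugar transferase gene (Os10g0442300) was 81.7-fold lower, a gene for a protein with a twin-arginine signal (Os01g0644000) 60.1-fold, and a bifunctional nuclease gene (Os01g0128200), whose kind of product degrades RNA and DNA, 39.5-fold. A glutathione S-transferase gene (Os10g0528100) was 49.7-fold lower and well above background on 3 of 4 knockdown arrays. NAC19 (Os07g0683200), a stress-response transcription factor, was at least 36.5-fold lower and a cytochrome P450 gene (Os10g0440000) at least 27.8-fold lower, neither being well above background on any knockdown array. Adjusted p-values ran from 0.0107 to 0.0134. Fold sizes depended on the processing, and not for dim genes alone. With the Feature Extraction processed signals, Os03g0286900 stood at -7.36, Os10g0442300 at -7.51 and Os05g0202800, which moved less, at -7.82. Among the rises, Os06g0289900 stood at 7.72, Os01g0294700 at 7.40 and OsEXPA2 at 6.85. RCc2, well above background on all 4 control arrays but with control log2 signals of only 7.19 and 6.87, stood at 10.63 against 9.77. Os07g0529600, bright in both lines, moved little, from -4.87 to -5.08.

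**Figure D2:**
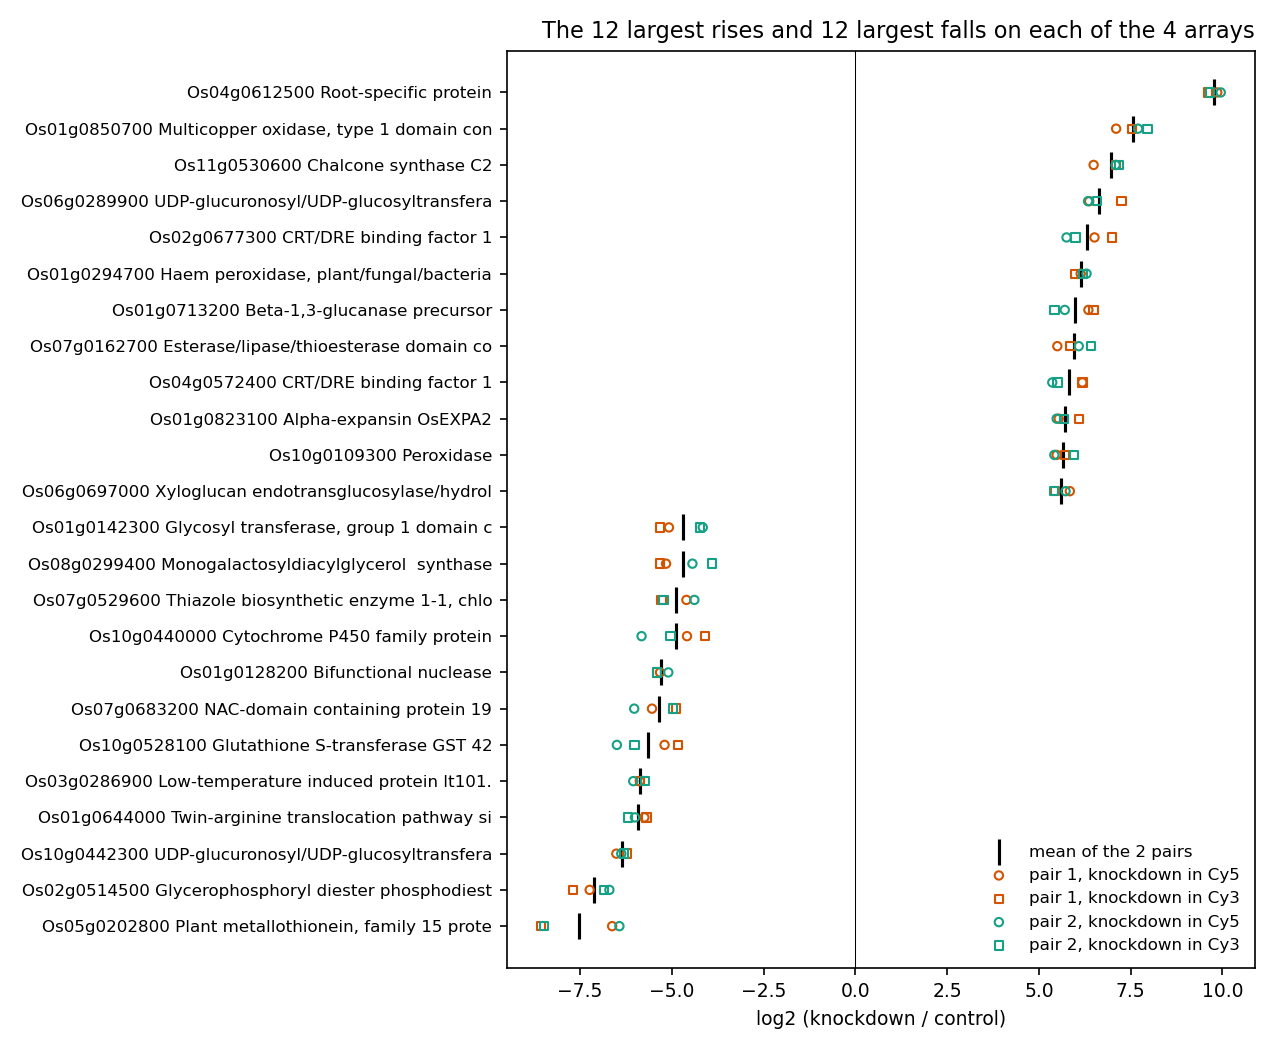
Log2 ratio of knockdown over control on each of the 4 arrays for the 12 largest rises and the 12 largest falls among called genes with a functional description. Symbols mark pair and dye orientation, vertical ticks the mean of the 2 pairs, which ran from -7.52 for a metallothionein gene to 9.77 for RCc2. Genes that were not well above background in one line have only a bound on the fold.

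The transcripts aimed at by the hairpin constructs were not analysed here, since 0 probe descriptions named MOM1 or its Arabidopsis full name; the labels were therefore not checked by the targeted genes. Transposable element genes did not shift as a group: of 77 measured, 7 rose, 10 fell and 60 did not pass, with a median log2 ratio of -0.01 (camera adjusted p = 0.472; 3 higher and 6 lower when adjusted over the list alone). Members with the largest changes were an En/Spm-like transposon gene (Os03g0714800), at least 4.87-fold higher, an IS4 transposase gene (Os08g0106900), at 2.20 ± 0.13, and a mutator-like transposase gene (Os09g0363200), at 1.59 ± 0.12. Among 19 genes of DNA methylation and RNA silencing, 6 rose and 3 fell (median 0.38, adjusted p = 0.420; 7 and 3 adjusted over the list alone). Argonaute 4 (Os07g0471300), which acts in RNA-directed DNA methylation, rose by 1.39 ± 0.12, and another Argonaute or Dicer gene with a PAZ domain (Os04g0615700) by 1.70 ± 0.19. A gene described as DEMETER (Os05g0445900), a glycosylase that removes methylated cytosine, was lower at -1.51 ± 0.16. Of 89 chromatin remodelling and histone modification genes, 10 rose and 8 fell (median -0.00, adjusted p = 1.00; 1 and 0 adjusted over the list alone). A jmjC gene (Os10g0577600) at 3.25 ± 0.19 and a jumonji gene (Os02g0696700) at 1.29 ± 0.15, both of a family that holds histone demethylases, were higher, and a SET domain gene (Os04g0423600), of the histone methyltransferase family, was lower at -1.86 ± 0.23. Core histone genes had a median of -0.32, with 7 higher and 11 lower of 39 (adjusted p = 0.115; 7 and 17 adjusted over the list alone). Histone H4 (Os02g0684500) stood at -1.58 ± 0.12, a gene described as histone H2A.F/Z (Os10g0418000) at -1.27 ± 0.16 and a histone H2B gene (Os01g0149600) at -1.25 ± 0.16.

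Genes of the photosystems and their light-harvesting antennae were higher in the knockdown leaves. Of 63 measured, 40 rose, 3 fell and 20 did not pass, with a median log2 ratio of 1.66, and camera called the list (adjusted p = 3.04e-08, with adjusted p = 0.729 with an estimated correlation; 46 higher and 3 lower adjusted over the list alone). Here and for the lists below, camera with an estimated correlation had 1 residual degree of freedom and could hardly call a list. The antenna protein gene CP24 (Os04g0457000) rose by 5.46 ± 0.50 and CP29 (Os07g0558400) by 4.58 ± 0.51, both minor chlorophyll-binding proteins of photosystem II. A major light-harvesting gene (Os01g0720500) rose by 5.41 ± 0.15 (n = 2 pairs). Of 18 genes described as chlorophyll a/b binding or light harvesting, 16 rose and 0 fell (median 2.82; limma, 45 other members: 24 higher, 3 lower), a division made after the list result was seen. The 3 members that fell were the photosystem II 10 kDa gene (Os07g0147500) at -4.01 ± 0.12, the photosystem II 22 kDa gene (Os04g0690800), whose product is needed to dissipate excess light as heat, at -3.47 ± 0.26, and a ferredoxin-NADP reductase gene (Os07g0147900) at -1.37 ± 0.12. The list median was 1.46 in pair 1 and 2.02 in pair 2, and the same genes stood 0.82 higher in control plant 1 than in control plant 2 (median log2 difference). Carbon fixation genes were split, with 4 higher and 4 lower of 21 (median 0.57, with 0.29 in pair 1 and 0.64 in pair 2; adjusted p = 0.901; 4 and 5 adjusted over the list alone), and were also higher in control plant 1, by a median of 0.66. Rubisco small subunit genes rose by 4.59 ± 0.67 (Os12g0274700), 3.68 ± 0.58 (Os12g0291400) and 2.21 ± 0.46 (Os12g0291100). The call of Os12g0291100 was lost with the scanner software's signals (adjusted p = 0.0627).

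Ribosomal protein genes moved the other way. Of 281 measured, 145 fell and 13 rose, with a median log2 ratio of -0.70 (camera adjusted p = 9.81e-12; adjusted p = 0.729 with an estimated correlation; 178 lower and 23 higher adjusted over the list alone). Among genes not described as plastid, 50S or 30S, 134 of 234 fell and 1 rose (median -0.77), whereas the 47 plastid-type members included 12 higher and 11 lower genes (median 0.35), or 6 and 12 with the scanner software's signals (median 0.26) and 12 and 14 with median centring (median 0.12); this division was made after the list result was seen. A gene of the L7Ae family (Os07g0636400) had the largest fall, -2.02 ± 0.14, while the 50S genes for L21 (Os02g0259600), described as a chloroplast precursor, at 2.13 ± 0.26, and L18 (Os03g0828100), at 1.91 ± 0.25, rose. The list median was -0.58 in pair 1 and -0.86 in pair 2. Between the control plants the plastid-type members were 0.62 higher and the others -0.38 (median log2, control plant 1 minus control plant 2).

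Defence genes that code for antifungal enzymes and pathogenesis-related proteins were higher in the knockdown plants. Of 98 members, 40 rose, 10 fell and 48 did not pass, with a median log2 ratio of 0.71 (0.68 with background-limited genes at their bound). Camera called the list (adjusted p = 0.000387, with adjusted p = 0.729 with an estimated correlation; 46 higher and 11 lower adjusted over the list alone). Chitinase genes counted 8 higher and 2 lower of 20 (4 and 3 with the scanner software's signals), glucanase genes 10 and 2 of 21, and thaumatin-type genes 7 and 1 of 16. A thaumatin-type gene (Os12g0569500) rose by 4.30 ± 0.52 (n = 2 pairs). PRB1-2 (Os01g0382400), a pathogenesis-related protein, was higher (adjusted p = 0.0361) by a fold that was not measured, being well above background on 2 of 4 control arrays, a call lost with the scanner software's signals (adjusted p = 0.0777). In this list, 24 members were ethylene-response-type transcription factors that carry the term pathogenesis-related in their description but are not defence proteins themselves, and of these 5 rose and 4 fell, against 35 and 6 of the other 74. These divisions were made after the list result was seen. Members of the list were lower in control plant 1 than in control plant 2, with a median difference of -0.25. Without a filter on dim probes the median was 0.10 and the call held (adjusted p = 0.0140).

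Receptor-like kinase genes, whose products sense signals at the cell surface, were higher too. Of 58, 28 rose and 4 fell (median 0.71; camera adjusted p = 0.000327; adjusted p = 0.729 with an estimated correlation; 32 higher and 6 lower adjusted over the list alone), and the median was 0.29 without a filter on dim probes. MARK (Os03g0223000), an atypical receptor-like kinase gene, rose by 4.33 ± 0.15 and receptor-like protein kinase 2 (Os03g0773700) by 3.66 ± 0.16. The S-locus type gene RLK10 (Os04g0632600) was lower at -2.63 ± 0.12. With the scanner software's signals these genes stood at 5.08, 4.68 and -2.85. The control plants differed by a median of -0.11 in this list. NBS-LRR resistance genes, which code for intracellular immune receptors, showed no shift, with 14 higher and 23 lower of 155 (median -0.06, adjusted p = 0.422; 8 and 14 adjusted over the list alone). Disease resistance genes Os11g0605100 and Os11g0229300, the latter well above background on 3 of 4 control arrays, rose by 2.55 ± 0.22 and 2.26 ± 0.16, and Os09g0517100, well above background on 2, by a fold that was not measured. WRKY transcription factor genes, many of them defence regulators, counted 8 higher and 7 lower of 54 (median 0.32, with 0.69 in pair 1 and 0.04 in pair 2; adjusted p = 0.483; 6 and 6 adjusted over the list alone). Os05g0537100 stood at 1.61 ± 0.27 and Os07g0596900 at -1.61 ± 0.12, and Os01g0186000 was lower by an amount not measured, being well above background on 1 of 4 knockdown arrays. The WRKY list was lower in control plant 1 by a median of -0.54, and without control plant 2 its median log2 ratio rose to 0.77. For Os05g0537100 the log2 ratio without control plant 1 was 0.77, against 1.61 with all plants.

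A list drawn up for diterpenoid phytoalexins, antimicrobial compounds of rice, held mostly higher genes: 11 of 17 rose and 2 fell (median 0.96, 0.95 with bounds). Camera called it (adjusted p = 0.0417, and adjusted p = 0.729 with an estimated correlation), with 11 higher and 3 lower adjusted over the list alone. The list was matched on descriptions and includes genes described only as terpene synthases, so a rise of phytoalexin synthesis itself was not shown. Kaurene synthase A (Os02g0278700), an enzyme at the entry to gibberellins and related diterpenoids, was at least 11.7-fold higher, and a terpene synthase gene (Os08g0139700) rose by 3.45 ± 0.26, whereas another (Os11g0286800) was lower at -3.49 ± 0.12. The list passed in 11 of 19 settings of camera. The call was lost with a stricter filter on dim probes (adjusted p = 0.0804), with 4 independent arrays (0.0585), with the mean of a gene's probes (0.0531), without control plant 1 (adjusted p = 0.0599), without knockdown plant 1 (adjusted p = 0.0542) and without knockdown plant 2 (adjusted p = 0.0537), while the median stayed between 0.89 and 1.02 in these settings, and it was lost without a filter on dim probes, where the median was 0.16 (adjusted p = 0.109). Jasmonate genes had 14 higher and 3 lower members of 32, or 16 and 3 adjusted over the list alone (median 0.93, 0.86 with bounds, camera adjusted p = 0.0797). Without a filter on dim probes the median of the jasmonate list was 0.19 (camera adjusted p = 0.109). Its leading members were ZIM domain genes, of the family of jasmonate signalling repressors, at 4.08 ± 0.60 (Os10g0391400), 3.58 ± 0.70 (Os03g0180900) and, well above background on 2 of 4 control arrays and without a measured fold, Os03g0180800 (call of Os03g0180900 lost with the scanner software's signals, adjusted p = 0.0573). Phenylpropanoid and lignin genes counted 11 higher and 6 lower of 37, or 12 and 6 adjusted over the list alone. Their median was 0.67, with 0.97 in pair 1 and 0.18 in pair 2 (camera adjusted p = 0.198), and 0.03 without a filter on dim probes (adjusted p = 0.479). Caffeoyl-CoA O-methyltransferase (Os08g0498400), a lignin enzyme, rose by 4.20 ± 0.12, phenylalanine ammonia-lyase (Os04g0518400), the entry enzyme of the pathway, by 4.06 ± 0.56, and a 4-coumarate CoA ligase gene (Os02g0697400) was at least 12.6-fold higher. All 3 lists were lower in control plant 1 than in control plant 2, by medians of -0.36, -0.70 and -0.52. Without control plant 2, the jasmonate list (adjusted p = 0.00410) and the phenylpropanoid list (adjusted p = 0.0112) passed, and with median centring the jasmonate list passed on all plants (median 0.70, adjusted p = 0.0239).

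Genes that loosen and build the cell wall were higher to a similar degree in both pairs. Of 60 wall expansion genes, 34 rose, 5 fell and 21 did not pass, with a median log2 ratio of 0.80 (0.76 with bounds) and a mean of 1.27. The medians of pair 1 and pair 2 were 0.90 and 0.91, and the control plants differed by a median of -0.10. Camera called the list (adjusted p = 1.45e-07, with adjusted p = 0.729 with an estimated correlation; 45 higher and 5 lower adjusted over the list alone). Expansin genes counted 10 higher and 1 lower of 15, xyloglucan genes 7 and 1 of 13, cellulose synthase genes 6 and 3 of 15, and pectin and other genes 11 and 0 of 17 (limma), a division made after the list result was seen. A gene described on the array as cellulose synthase CesA-1 (Os04g0429600) went against the list at -4.66 ± 0.44 (25.2-fold lower, n = 2 pairs). Its identity was not checked beyond that description. The median was 0.05 without a filter on dim probes (adjusted p = 0.00996) and 1.98 with the scanner software's signals.

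**Figure D3:**
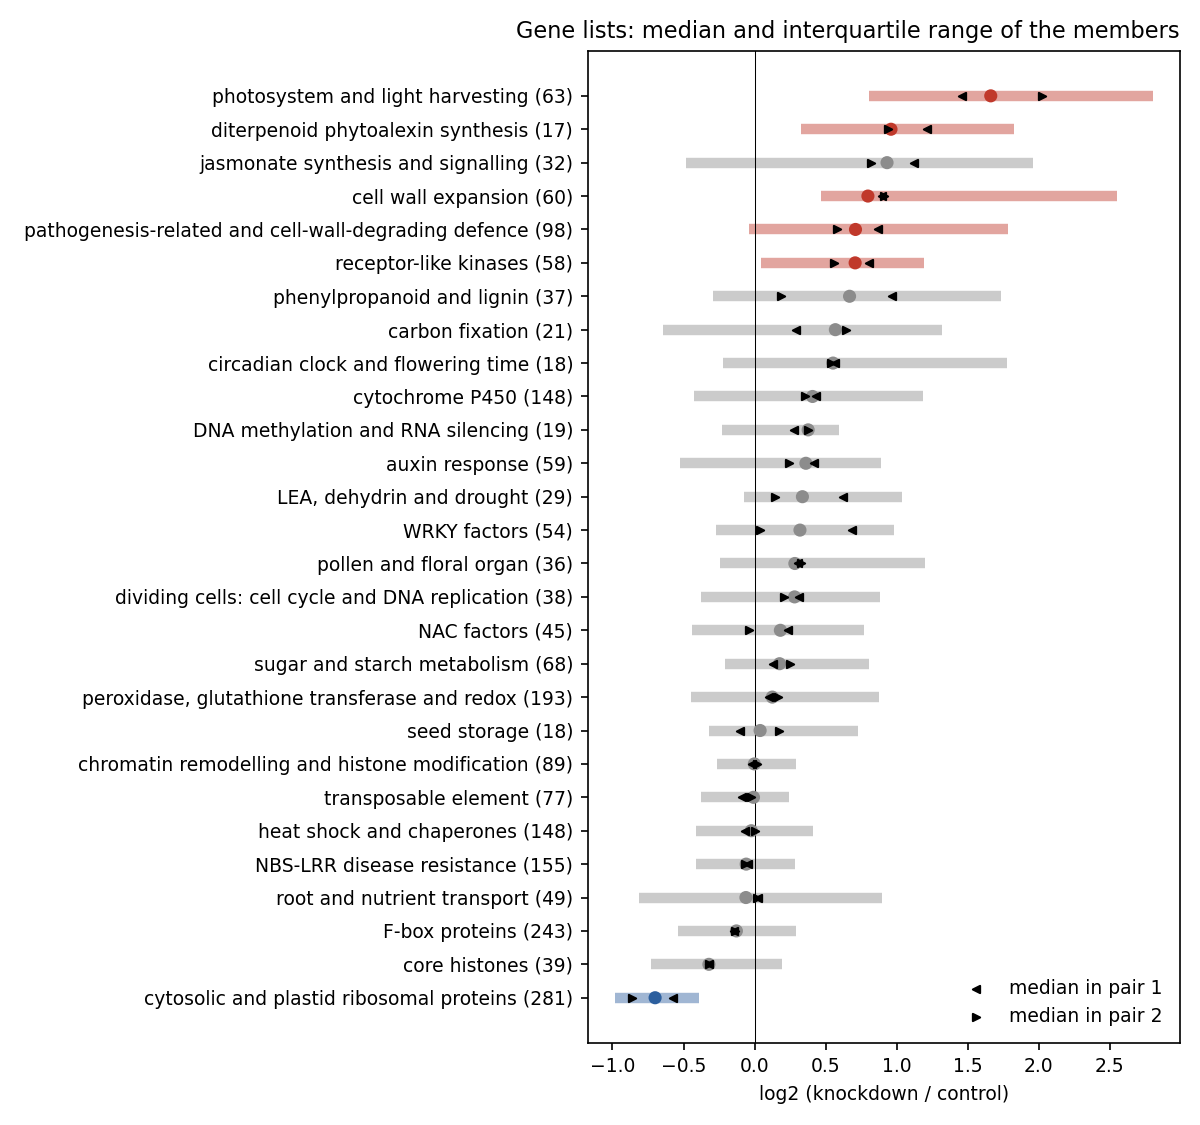
Median log2 ratio of knockdown over control (points) and interquartile range of the members (bars) for each gene list, with the number of measured genes in parentheses and the medians of pair 1 and pair 2 as arrowheads. Coloured lists passed camera with a preset correlation, from 1.66 for photosystem genes to -0.70 for ribosomal proteins. None passed with an estimated correlation (lowest adjusted p = 0.729), where 1 residual degree of freedom left camera hardly able to call a list.

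Other stress and metabolic lists held strong changes of single genes but did not pass as lists. Cytochrome P450 genes had 58 higher and 28 lower of 148 (median 0.41, adjusted p = 0.0739; 63 and 30 adjusted over the list alone), among them flavonoid 3'-monooxygenase (Os10g0320100), a flavonoid-modifying enzyme, at 4.65 ± 0.31 and an elicitor-inducible P450 (Os09g0441400) at 3.51 ± 0.42. That list passed with the scanner software's signals (adjusted p = 0.0232), the deposited table (0.0233), median centring (0.00744) and an offset of 0 (0.0470), as well as without control plant 2 (0.0374) and without knockdown plant 2 (0.0351). Without a filter on dim probes the median of the cytochrome P450 list was 0.06, and it did not pass camera (adjusted p = 0.181). Peroxidase, glutathione transferase and redox genes counted 53 higher and 40 lower of 193 (median 0.12, adjusted p = 0.420), or 56 and 41 adjusted over the list alone. Sugar and starch genes had 19 higher and 8 lower of 68 (median 0.18, adjusted p = 0.197; 19 and 8 adjusted over the list alone). Trehalose-6-phosphate phosphatase (Os02g0661100), which completes trehalose synthesis, rose by 4.69 ± 0.36, an invertase inhibitor gene (Os08g0108100) by 3.22 ± 0.69 (call lost with the scanner software's signals, adjusted p = 0.0594) and a beta-amylase gene (Os10g0565200) by 2.73 ± 0.17. Heat shock and chaperone genes were balanced, with 28 higher and 24 lower of 148 (median -0.02, adjusted p = 0.738; 27 and 24 adjusted over the list alone), and included HSP70 (Os11g0703900) at -3.95 ± 0.14, a 16.9 kDa small heat shock protein gene (Os01g0136100) at -2.68 ± 0.13 and heat shock factor 21 (Os03g0161900) at 2.42 ± 0.12. LEA, dehydrin and drought genes had 9 higher and 0 lower of 29 in limma (median 0.34, with 0.63 in pair 1 and 0.14 in pair 2; adjusted p = 0.118; 7 and 0 adjusted over the list alone). WSI76 (Os03g0316200), a water-stress gene, rose by 2.56 ± 0.53 (call lost with the scanner software's signals, adjusted p = 0.0530), dehydrin COR410 (Os02g0669100) by 2.20 ± 0.23 and an abscisic acid inducible gene (Os08g0467500) by 2.02 ± 0.17. The LEA list was lower in control plant 1 by a median of -0.46 and passed without control plant 2 (median 0.53, adjusted p = 0.00693). NAC transcription factor genes had 12 higher and 10 lower of 45, with a median of 0.18 (0.23 in pair 1 and -0.04 in pair 2) and a mean of -0.13 (adjusted p = 0.798; 12 and 10 adjusted over the list alone), and NAC29 (Os03g0327800) stood at -3.56 ± 0.33 and a NAM gene (Os11g0126900) at -4.24 ± 0.38. The control plants differed by a median of -0.34 in NAC genes.

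Lists chosen as markers of growth state, other organs or sampling time gave no call. Among 59 auxin genes, 21 rose and 12 fell (median 0.36, adjusted p = 0.198; 23 and 16 adjusted over the list alone). A SAUR gene (Os09g0546000) rose by 3.83 ± 0.38 and an Aux/IAA gene (Os12g0601400), well above background on 2 of 4 control arrays, by a fold that was not measured. Dividing-cell genes had 17 higher and 5 lower of 38 (median 0.28, adjusted p = 0.198; 17 and 10 adjusted over the list alone), but 15 of the 17 were kinesins, motor proteins with roles beyond division (10 kinesins higher and 6 lower with the scanner software's signals), led by Os08g0547500 at 4.24 ± 0.15, Os01g0625200 at 2.45 ± 0.12 and Os09g0528000 at 2.31 ± 0.15. In the clock and flowering list, 9 rose and 3 fell of 18 (median 0.55, adjusted p = 0.198; 9 and 3 adjusted over the list alone), and all 9 were CONSTANS-type zinc finger genes, a family that reaches beyond flowering control. That family made up 16 of the 18 genes (9 higher, 2 lower, median 0.99), a division made after the list result was seen. The clock and flowering list therefore says little about sampling time. CONSTANS-like 1 (Os02g0731700) rose by 5.09 ± 0.19, Os06g0264200 by 4.58 ± 0.29 and Os02g0724000 by 2.11 ± 0.17. F-box genes counted 33 higher and 56 lower of 243 (median -0.13, adjusted p = 0.183; 33 and 57 adjusted over the list alone), with Os03g0321300, Os01g0806200 and Os08g0150700 at 3.02 ± 0.12, 2.20 ± 0.26 and 2.10 ± 0.38, the last call being lost without a filter on dim probes (adjusted p = 0.0534). Seed storage genes had 5 higher and 3 lower of 18 (median 0.04, with -0.10 in pair 1 and 0.17 in pair 2; adjusted p = 0.901; 5 and 3 adjusted over the list alone), namely a glutelin gene (Os03g0188500) at 2.61 ± 0.50 (call lost without a filter on dim probes, adjusted p = 0.0598), an amylase or trypsin inhibitor gene (Os03g0661600) at least 2.07-fold higher (0.0506 without that filter) and a cupin gene (Os03g0654700) at least 6.15-fold lower among them. Pollen and floral genes had 11 higher and 8 lower of 36 (median 0.28, adjusted p = 0.195; 11 and 8 adjusted over the list alone), among them a MADS-box gene that was well above background on 1 of 4 control arrays and whose fold was therefore not measured (Os01g0726400, higher), another at 2.01 ± 0.24 (Os07g0605200) and a pollen allergen type gene (Os10g0371000) at 2.02 ± 0.12. Root and nutrient transport genes had 14 higher and 12 lower of 49, with a median of -0.06 and a mean of 0.22 (adjusted p = 1.00; 17 and 17 adjusted over the list alone), with RCc2 and a metallothionein gene (Os12g0571100, at least 19.9-fold higher) at one end and the metallothionein gene Os05g0202800 at the other.

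The knockdown plants resembled each other more closely than the control plants did. Log2 signals of the 2 knockdown plants correlated across probes with r = 0.997 and differed with an SD of 0.18, and 68 probes differed over 2-fold. For the 2 control plants r was 0.967, the SD of the difference 0.58, and 2149 probes differed over 2-fold. The ratio itself had an SD of 1.10 in pair 1 and 1.09 in pair 2. Arrays of the same pair with exchanged dyes correlated with r = 0.976 in both pairs. Of 20475 genes seen in either line, 514 were well above background on all arrays of the knockdown line alone and 468 in the control line alone, with 2 transposable element genes in each of these sets.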

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

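No probe called here was called in the opposite direction under any alternative, and the correlation between the pairs stayed between 0.863 and 0.889. Medians of several lists without a call changed sign between alternatives, as for WRKY factors (-0.12 to 0.77), NAC factors (-0.13 to 0.24), redox genes (-0.07 to 0.23) and seed storage genes (-0.18 to 0.22). The larger share of calls turned from higher to lower with the scanner software's signals (4880 higher, 5812 lower) and with median centring (5080 and 6473). The photosystem, ribosomal, wall, defence and receptor-like kinase lists passed camera under every processing alternative. With an estimated correlation, 0 lists higher and 0 lower passed (lowest adjusted p = 0.729, 0 at an unadjusted p under 0.05). That form of camera used the 1 residual degree of freedom and could hardly call any list, so its lost calls do not decide whether a list shifted. The wall list did not pass although its estimated correlation was -0.012, below the preset 0.01. Other called lists had estimates well above the preset, at 0.41 for photosystem, 0.31 for ribosomal, 0.24 for diterpenoid and 0.16 for pathogenesis-related genes. For those lists the adjusted p-values of camera at the preset may be far too small. With fry in one direction, 0 and 0 passed (lowest adjusted p = 0.0871, 10 at an unadjusted p under 0.05). Fry tests a list against no change and not against other genes, and 26 of 28 lists passed its test for changes in mixed directions. Treating the 4 arrays as independent gave 10124 higher and 9395 lower probes, because spread between arrays then counted as replication. The pair as a random block without a dye term, added after the data were seen, gave 8949 higher and 7755 lower. Per-channel values with the replicate block gave 6015 and 4948, the same by construction as the paired ratios. Without the block they gave 6609 and 5985, and the diterpenoid list did not pass camera (adjusted p = 0.0577). Leaving out 1 plant gave 0 to 10431 higher and 0 to 9533 lower probes and 4 to 10 higher lists. By construction the spread then came from the line with 2 plants left, and the knockdown plants differed less than the control plants. An added 2-fold threshold left 3800 and 2475, and 3957 genes stood for the higher probes.

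Probes over 2-fold on all 4 arrays numbered 3606 higher, 3180 lower and 32 opposite with the scanner software's signals, and 3597, 3172 and 32 with the deposited table; the cause was not tested. In pair 2 alone 2592 were lower and in pair 1 alone 2260. At 1.5-fold the counts were 5210, 3759 and 82 (higher, lower, opposite) and at 3-fold 1482, 588 and 4. For genes not well above background in one line only a bound on the fold is given, while the call comes from the ratio itself. No spot was saturated. Without the filter on dim probes, calls of Os03g0188500 (adjusted p = 0.0598), Os03g0661600 (0.0506), Os08g0150700 (0.0534), Os01g0382400 (0.0559), Os03g0180900 (0.0616), Os08g0108100 (0.0715), Os03g0316200 (0.0665) and Os12g0291100 (0.0663) were lost. Without the replicate block, those of Os03g0188500 (0.0742), Os01g0382400 (0.0647), Os10g0391400 (0.0530), Os08g0108100 (0.0720) and Os05g0537100 (0.133) were lost.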

Other observations

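In the order of the tested genes, changed genes followed one another more often than in shuffled orders. Among 20374 adjacent pairs, 1688 changed in one direction against 1352 in shuffled orders (SD 30.7). The longest run held 9 higher genes on chromosome 6, from Os06g0640100 to Os06g0642900 (median log2 ratio 1.53), and the longest run of lower genes held 6 on chromosome 5, from Os05g0485300 to Os05g0486700 (median -1.20). Order was taken from locus numbers, as coordinates were not given in the sources used here. Only the 20386 tested genes were ordered, out of 29690 loci on the array. Untested loci can therefore lie between the genes of a pair or run, and the runs need not be unbroken blocks.

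Single genes differed strongly between the control plants (control plant 1 minus control plant 2, log2). A ZIM domain gene (Os07g0153000), of the family of jasmonate signalling repressors, stood 5.28 higher, while WRKY genes Os09g0417600 and Os01g0826400 stood at -5.08 and -3.87, a RING finger gene (Os02g0559800) at -4.82, an amino acid transporter gene (Os01g0597600) at -4.74, isocitrate lyase (Os07g0529000) at -4.55 and a beta-1,3-glucanase gene (Os01g0940800) at -3.89. These genes were chosen after the control plants had been compared.

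The tests of sampling time and array noise were written after the results were seen, and the others before. Sampling time could have contributed to the difference between the lines, which the data cannot tell: the median absolute log2 ratio of 3 clock genes was 0.639, with FKF1 (Os11g0547000) at -2.78, GIGANTEA (Os01g0182600) at -0.64 and a pseudo-response regulator gene (Os03g0284100) at -0.26. A large difference in RNA degradation was unlikely, since probes nearer the start of 664 genes differed from 3' probes by a median of -0.12 (95% interval -0.13 to -0.10). The whole interval was negative, so a small difference remained possible. That interval covers the spread between genes and not between plants. Later senescence of the control leaves could not be told either, with a median log2 ratio of 0.0238 (95% interval -0.25 to 0.30) over 26 genes, 5 higher and 5 lower. This median hides a split. The lower genes included red chlorophyll catabolite reductases Os10g0389200 (-3.16) and Os10g0389100 (-3.07) and a chlorophyllase family gene (Os10g0419600, -1.36). Among the higher were an isocitrate lyase family gene (Os12g0189300, 3.53) and genes for senescence-associated proteins 12 (Os03g0241900, 1.99) and 15 (Os03g0245700, 1.94). Isocitrate lyase genes were themselves split. Another gene of that family (Os04g0504600) was called lower at -1.90, and isocitrate lyase Os07g0529000 stood at -3.85 without passing (limma adjusted p = 0.104).

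Array noise was an unlikely source of the control plants' difference, which correlated across probes with r = 0.962 between the dye orientations. Across all probes it did not follow the direction of the line difference (r = -0.0587), but its sign varied between lists. The medians of photosystem genes (0.82) and of ribosomal genes not of plastid type (-0.38) had the sign of the line difference, and those of jasmonate (-0.70) and pathogenesis-related genes (-0.25) the opposite sign.

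For neighbouring genes the permutation test gave p = 0.0001, the smallest possible with 10000 draws, and 75.8% of the excess was left without pairs that share a description. Copies without a functional description could not be left out in this way. Whether neighbouring genes share regulation was not tested. No enrichment of transposable element genes was seen among genes seen in the knockdown alone (Fisher's exact p = 0.720, odds ratio 1.04, 95% interval 0.123 to 3.89). With only 2 such genes in that set, the test could not exclude an enrichment within that interval.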
